A study of Paraburkholderia caribensis with 5 samples.

How the data were processed

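RNA-seq read counts were used from 5 libraries of P. caribensis MBA4 grown on 3 carbon sources, MCA (2 libraries), glycolate (2) and pyruvate (1). Per the labels, total RNA came from log-phase cells, ribosomal RNA was removed with a bacterial mRNA enrichment kit, and Illumina libraries were made from the rest. Groups and replicate numbers came from the labels. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

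Per the file headers, each file lists a feature identifier, its position, unique and total gene reads, an expression value and an RPKM. The read columns hold raw counts per feature as deposited by the authors, and the unique and total counts were identical for every feature. The RPKM and expression columns as deposited were identical to each other and returned each file's own read total when multiplied back by feature length. The deposited first-set files also hold a normalized signal, which had the same sorted values in all 3 files and so had been put on a common distribution by the authors. Only the counts entered tests. The aligner, the counting program, the strand setting and the genome build are not given in the sources used here. How reads of overlapping or antisense genes and of near-identical copies were assigned is therefore not known. The equal unique and total counts show no sign of reads counted at several places, but how such reads were handled is not given.

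The first set (MCA 1, glycolate 1, pyruvate 1) lists 9112 features on 12 scaffolds, and the second set (MCA 2, glycolate 2) 9152 features on 2 chromosomes and 1 plasmid. Of 9035 shared identifiers, 8963 had the same length in both sets and were joined, and 72 had another length. A further 77 identifiers were listed only in the first set and 117 only in the second. Of 8960 pairs of neighbours among the joined genes on the replicons of the second set, 8954 (99.93%) were also neighbours on the scaffolds. The joined genes held 98.96% to 99.39% of each library's counted reads. Positions are those of the second set, counted from 1, and the build behind them was not named in the files.

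Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (8197 genes), scaled by TMM and tested with glmQLFit and glmQLFTest on 1 factor for the carbon source over all 5 libraries, with 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene passed at an adjusted p under 0.05, with a further count at 2-fold or more. The same fit with the file set as an added term had 1 residual degree of freedom. It is given beside the first fit because the files were made differently in the 2 sets, and it was planned as a fit with the replicate number. The common dispersion was 0.223 without the term and 0.0596 with it. Standard errors are the log2 fold change divided by the square root of the F statistic and are approximate. CPM values use TMM-scaled library sizes, and log2 CPM has a prior count of 2. The fold of a region is the ratio of the mean summed CPM of its tested genes, and its read share is taken over the reads of the joined genes.

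The lowest level that 3 reads allow was 0.165 CPM in MCA 1, 0.169 in glycolate 1, 0.683 in pyruvate 1, 0.498 in MCA 2 and 0.501 in glycolate 2 before TMM scaling, and 0.928 CPM in pyruvate 1 after it. Features with 0 reads numbered 349, 318, 952, 272 and 251 in the same order, so low genes are least certain in pyruvate. The 20 genes with most reads took 17.4%, 16.9%, 24.0%, 18.7% and 19.1% of the joined reads. Wilson intervals of read shares at 95% and the floors cover counting error only.

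The fits were tested on simulated libraries with 50 genes changed at each of 4 fold sizes. The counts were simulated with the set differences and dispersions of the fit with the file set term, and with pyruvate in the first set. The fit with the term was thus right by construction. The values below therefore cannot show which fit suits the real libraries, where false calls may be more frequent. Without the file set term, 0% of 4-fold and 30% of 16-fold changes between MCA and glycolate were recovered, over 8095 genes. With it, 24% of 2-fold, 86% of 4-fold and 100% of 16-fold changes were recovered, and 22 of 176 calls were false. For MCA against pyruvate, over 8092 genes, 0% of 64-fold changes were recovered without the term and 64% of 4-fold changes with it, with 12 of 138 calls false. For glycolate against pyruvate, over 8102 genes, 32% of 64-fold changes were recovered without the term and 62% of 4-fold changes with it, with 8 of 134 calls false.

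Before the data were examined, 24 gene lists were fixed, among them haloacid dehalogenation, haloacid uptake, glycolate oxidation, the glyoxylate shunt, heat shock, ribosomal proteins and stable RNAs. The files give identifiers without gene or product names for the joined genes, so 0 lists matched a joined gene and no list was tested. Of the stable RNAs, only the 8 ribosomal RNA features of the first set are named, and these are not among the joined genes. The rule for named genes was also fixed then. It takes the largest changes in each direction among genes that passed the fit without the file set term. These need a mean of at least 10 CPM and groups that do not overlap. Where too few passed, the largest other such changes fill the list. At most 2 identifiers are named in each direction where product names are missing. As 0 genes passed in any comparison, every named gene was a fill, ranked by its log2 fold change without the term. Positions were grouped after the data were seen: a block is a run of at least 4 neighbouring tested genes called in the same direction with the file set as a term, and blocks less than 50 kb apart were joined to a window.

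The alternatives were DESeq2 and upper quartile size factors, no filter, at least 50 reads in 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, each replicated library left out, the 20 highest genes left out, only the MCA and glycolate libraries, and stricter thresholds for the overlap. Chosen after the data were seen were all shared identifiers and repeats of these settings with the file set as a term, among them equal depth and leaving out the pyruvate library. The overlap was set against independent lists and against 20 simulations of unchanged groups. The number of blocks was set against 1000 shuffles of the calls within each replicon. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.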

Results

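Messenger RNA levels were measured by RNA-seq in Paraburkholderia (Burkholderia) caribensis MBA4, a bacterium that can use haloacetates for growth. Its haloacid dehalogenase activity turns monochloroacetate (MCA) into glycolate, so cells on glycolate receive the product of dehalogenation without the halogenated substrate. The series addresses how this strain breaks down chloroacetate, with cells in log phase at 30 °C in minimal medium holding 0.5 g of carbon per litre as MCA, glycolate or pyruvate. MCA and glycolate had 2 libraries each and pyruvate had 1. The libraries came as 2 file sets. The first set held MCA 1 with 18317419 reads counted in features, glycolate 1 with 17895468 and pyruvate 1 with 4437531, all counted on scaffolds. The second set held MCA 2 with 6057482 reads and glycolate 2 with 6031107, counted on chromosome 1, chromosome 2 and a plasmid. The replicate number and the file set were therefore the same split. Across the 8197 genes tested, log2 levels correlated at r = 0.915 between the MCA libraries and r = 0.897 between the glycolate libraries, but at 0.942 and 0.951 between MCA and glycolate within the first and second sets. These correlations run across genes, which are not independent replicates. Because of that split, each comparison is given with and without the file set as a term. A gene is said to be called where its adjusted p was under 0.05 in the fit with the term. The planned main fit was the one without the term, and 0 genes passed it in each comparison. Taking the fit with the term as the basis for calls, blocks and windows was not planned. The files pair no gene or product names with the identifiers of the genes tested, so genes are grouped below by position on the replicons of the second set.

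MCA was compared with glycolate to separate growth on the halogenated acid from growth on its product. A 68.8 kb window of chromosome 2 from 2239101 to 2307926, holding 57 tested genes, took 4.92% ± 0.12 (SD, n = 2) of the reads in MCA and 0.578% ± 0.214 (SD, n = 2) in glycolate. Its summed CPM was 10.5-fold higher in MCA, with 16.8-fold in the first set and 7.05-fold in the second. Of its 57 genes, 28 were called higher in MCA and 0 lower, and the called genes had log2 fold changes from 1.16 to 7.51. Another 25 genes of the window differed by less than 2-fold, so the largest excess sat in blocks of neighbouring genes. MCA stood above glycolate in both sets for 51 of the 57 genes, so many genes between the blocks shared the direction at a smaller size.

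By mean summed CPM over the 2 sets, the block with the widest gap covered 5 genes at the end of the window, from 2301385 to 2307926. It held 1.18% ± 0.124 (SD, n = 2) of the reads in MCA and 0.0142% and 0.0141% in the glycolate libraries, a 103-fold difference that was 110-fold in the first set and 95.5-fold in the second. Within it, K788_000561 at 2303110 to 2304768 stood at 5514 ± 66.0 CPM (SD, n = 2) in MCA against 36.3 ± 0.01 (SD, n = 2) in glycolate, and K788_000560 at 2305121 to 2305816 at 6221 ± 701 CPM (SD, n = 2) against 34.4 ± 7.1 (SD, n = 2). Their log2 fold changes were 7.25 (SE 0.51) and 7.50 (SE 0.55), each with an adjusted p of 0.0611 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the file set as a term the adjusted p of both was 0.000938, and over all its alternatives it ran from 1.55e-53 to 0.145 for K788_000561 and from 5.65e-52 to 0.145 for K788_000560. A block of 8 genes from 2267120 to 2276862 was 35.0-fold higher in MCA, at 35.5-fold and 34.4-fold in the first and second sets. A block of 4 genes from 2239101 to 2243490 was 69.2-fold higher, at 122-fold and 36.5-fold, and so had the wider gap in the first set. The median log2 fold change of its genes with the term was 5.81, against 4.31 in the 5-gene block. The 10 genes from 2245922 to 2257013 were 6.0-fold higher, at 14.1-fold in the first set and 3.68-fold in the second.

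**Figure D1:**
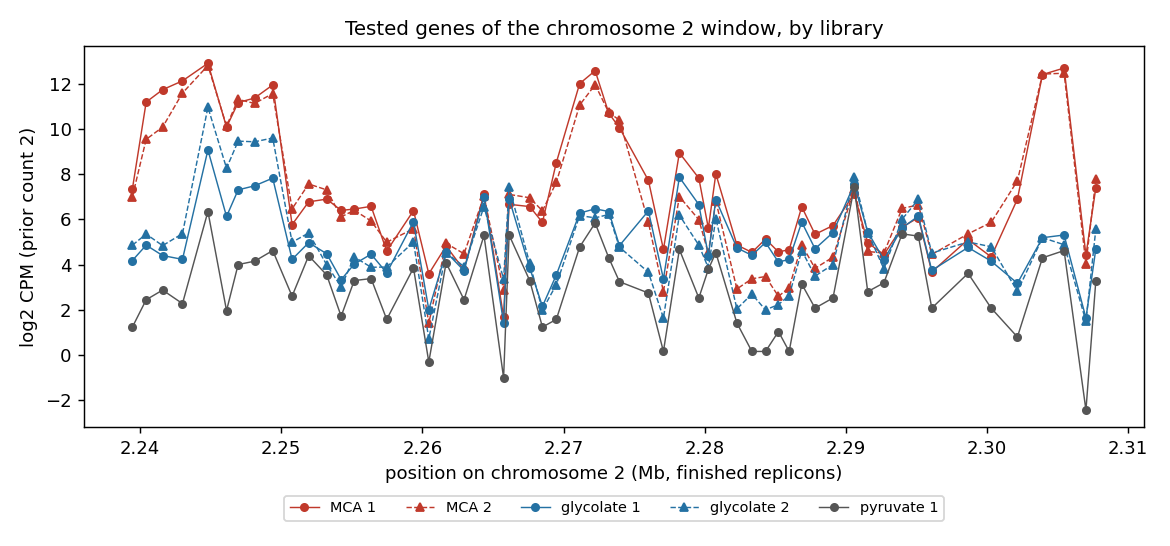
Level of each of the 57 tested genes of the chromosome 2 window in each of the 5 libraries, as log2 CPM with a prior count of 2 (vertical axis) against the middle of the gene in Mb (horizontal axis). Points are genes of 1 library, lines only join neighbours, circles are first-set and triangles second-set libraries. Within each set, MCA lies above glycolate in the blocks and mostly nearer to it between them. Some glycolate 1 values lie above those of MCA 2, also inside a block.

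Of the 260 genes called lower in MCA, 52 lay in blocks. On chromosome 1, 16 neighbouring genes from 2624562 to 2635981 were all called lower, with log2 fold changes of median -2.56. They took 0.147% ± 0.115 (SD, n = 2) of the reads in MCA and 0.863% ± 0.321 (SD, n = 2) in glycolate, and their summed CPM was 5.09-fold higher in glycolate, at 6.77-fold and 4.5-fold within the first and second sets. On the plasmid, 7 genes from 1152512 to 1158313 were 4.57-fold higher in glycolate, at 6.61-fold and 3.83-fold, with 0.0949% ± 0.0728 (SD, n = 2) of the reads in MCA and 0.504% ± 0.130 (SD, n = 2) in glycolate. Of the single genes taken by the naming rule, K788_003837 on chromosome 1 at 2829556 to 2829909 had a log2 fold change of -4.86 (SE 1.67) with an adjusted p of 0.741 (edgeR quasi-likelihood), and of -3.74 with an adjusted p of 0.0174 with the file set as a term. Glycolate 1 held 4.58 CPM and glycolate 2 held 144 CPM of it, and without glycolate 2 the log2 fold change was -0.76. Its log2 ratios within the sets were -1.86 and -5.06, and its adjusted p ran from 0.00571 to 0.999 over all its alternatives. K788_004943 on chromosome 1 at 1560603 to 1562252 passed neither fit, with a log2 fold change of -4.41, adjusted p values of 0.741 and 0.0593 by edgeR without and with the term, and within-set ratios of -5.06 and -1.16. It stood at 398 CPM in glycolate 1 and 17.4 CPM in glycolate 2, and without glycolate 1 its log2 fold change was -0.80. Its adjusted p ran from 0.00435 to 1 over all its alternatives.

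Over the genome, 413 of 8197 genes were called between MCA and glycolate with the file set as a term, 153 higher and 260 lower in MCA and all by at least 2-fold. With DESeq2 size factors in place of TMM the split was 284 higher and 316 lower, and with DESeq2 in place of edgeR it turned to 321 higher and 268 lower. With all libraries thinned to equal depth, 1049 genes were called, 462 higher and 587 lower. Without the term, edgeR called 0 genes, with 546 at an unadjusted p under 0.05, while DESeq2 called 113, limma-voom 5, and edgeR 0 to 7 with any 1 replicated library left out. Within the sets, the log2 ratios of MCA to glycolate correlated across genes at r = 0.551 (Spearman's rho 0.504). MCA was at least 4-fold higher in both sets for 36 genes, where independent sets would give 1.03, and at least 4-fold lower in both for 38, where they would give 1.99. Another 4 genes passed 4-fold in opposite directions. The fit with the term had 1 residual degree of freedom, and on simulated libraries 22 of its 176 calls for this comparison were false. Those libraries were simulated under the model of that fit, so the share of false calls among the 413 may be higher.

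**Figure D2:**
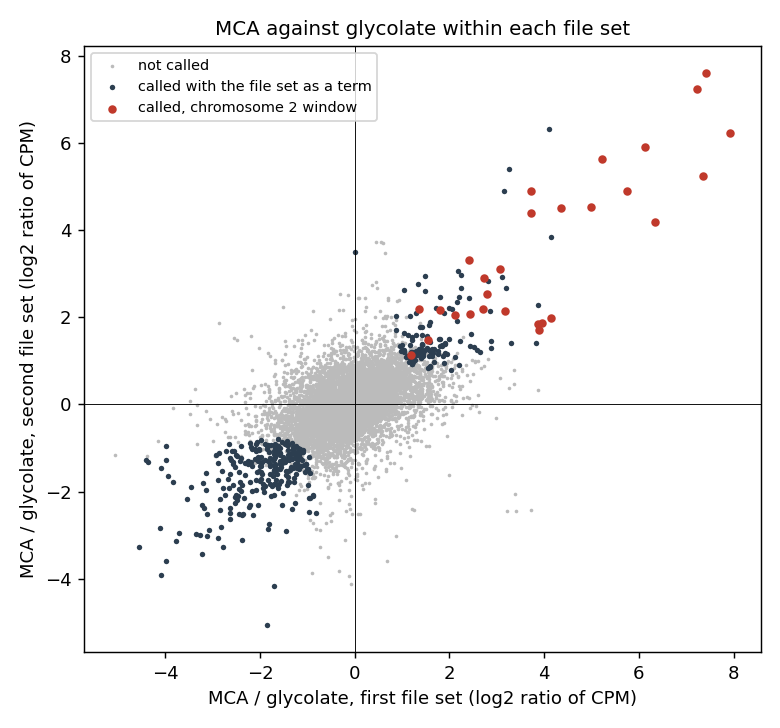
Log2 ratio of CPM in MCA over glycolate in the first file set (horizontal axis) and in the second (vertical axis), with 1 point for each of the 8197 tested genes. Dark points are genes called with the file set as a term and red points are the 28 called genes of the chromosome 2 window, which lie above 0 in both sets.

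MCA was next compared with pyruvate, which serves as a carbon source outside the dehalogenation route. A block of 6 genes on chromosome 1 from 2386239 to 2393626 took 1.58% ± 0.603 (SD, n = 2) of the reads in MCA and 0.00588% in the pyruvate library (95% Wilson interval 0.0052 to 0.00664), a 211-fold difference in summed CPM that was 288-fold within the first set and 134-fold for MCA 2. The chromosome 2 window at 2239101 to 2307926 was 55.9-fold higher in MCA than in pyruvate, where it held 0.0672% of the reads (95% Wilson interval 0.0648 to 0.0697), and 49 of its 57 genes were called higher and 0 lower. In the other direction, 15 neighbouring genes of chromosome 2 from 1620861 to 1652894 held 2.15% of the pyruvate reads (95% Wilson interval 2.13 to 2.16) and 0.0179% ± 0.0141 (SD, n = 2) in MCA, which made them 167-fold higher in pyruvate, 321-fold against MCA 1 of the same set and 113-fold against MCA 2.

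Of the genes in that block, K788_006294 at 1624532 to 1625998 stood at 2368 CPM in pyruvate and 7.16 ± 4.88 CPM (SD, n = 2) in MCA, a log2 fold change of -8.38 (SE 0.87) with an adjusted p of 0.0758 by edgeR's quasi-likelihood test. These were -9.07 and 0.000103 with the file set as a term, and the log2 fold change was -7.80 without MCA 1 and -9.31 without MCA 2. K788_006291 at 1631991 to 1641587 stood at 11035 CPM in pyruvate and 40.02 ± 38.89 CPM (SD, n = 2) in MCA, with a log2 fold change of -8.11 (SE 1.30) and an adjusted p of 0.127 by edgeR. With the term these were -9.58 and 0.000198, and the log2 fold change was -7.35 without MCA 1 and -9.78 without MCA 2. Over all alternatives the adjusted p ran from 2.39e-23 to 0.0888 for K788_006294 and from 1.94e-12 to 0.14 for K788_006291. The genes of the naming rule that were higher in MCA had 0 reads in the pyruvate library, so only lower bounds against a floor of 3 reads are given. K788_007740 on chromosome 1 at 1106608 to 1106724 was at least 47.2-fold higher in MCA on average and at least 17.2-fold within the first set. K788_0020435 on chromosome 1 at 427723 to 427908 was at least 52.6-fold higher on average but at least 2.99-fold within the first set, since MCA 1 held 2.77 CPM and MCA 2 held 94.9 CPM. With the file set as a term their adjusted p values by edgeR were 0.00224 and 0.0159, and over all its alternatives they ran from 0.00224 to 0.575 and from 0.0159 to 0.779.

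In some blocks the file sets differed as well as the carbon sources. A block of 6 genes of chromosome 2 from 319209 to 326119 held 4.34% of the reads in pyruvate (95% Wilson interval 4.32 to 4.36). It held 0.00467% in MCA 1 and 0.00585% in glycolate 1, but 2.95% in MCA 2 and 2.8% in glycolate 2. On chromosome 1, 4 genes from 989901 to 993658 held 4.46% in pyruvate (95% Wilson interval 4.43 to 4.47), 0.164% in MCA 1, 0.128% in glycolate 1, 0.862% in MCA 2 and 1.56% in glycolate 2, so that pyruvate stood above every other library.

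With the file set as a term, 1157 genes were called between MCA and pyruvate, 680 higher and 477 lower in MCA, all by at least 2-fold in that fit. At equal depth 1780 were called, 1025 higher and 755 lower. The pyruvate library lay outside both MCA libraries for 656 of the 680 and for 433 of the 477. It lay at least 2-fold beyond both for 554 of the 680 and for 290 of the 477. The genes were called from these same libraries, so such counts are no independent check of the calls. The fit assumes that the set difference includes the pyruvate library, which the data could not settle. Without the term, edgeR called 0 genes, with 1062 at an unadjusted p under 0.05, while DESeq2 called 297, limma-voom 23, and edgeR 5 to 72 with any 1 replicated library left out. The lone pyruvate library was assumed to vary like the replicated groups, although its ratio of 16S_2 to 23S_2 reads was 14 against 0.735 in MCA 1 and 0.567 in glycolate 1. Only the first set holds it, where MCA was at least 4-fold higher for 689 genes and at least 4-fold lower for 184.

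Glycolate was compared with pyruvate in the same way, to follow growth on the product of dehalogenation. The chromosome 1 block was again far above pyruvate, with 5 of its genes from 2386239 to 2392533 at 2.1% ± 0.109 (SD, n = 2) of the reads in glycolate and 0.00387% in pyruvate (95% Wilson interval 0.00333 to 0.0045), a 333-fold difference that was 306-fold within the first set. All 16 genes of chromosome 1 from 2624562 to 2635981, which were lower in MCA than in glycolate, were called higher in glycolate than in pyruvate and were 55.7-fold higher in sum, 38.8-fold within the first set. On the plasmid, 9 genes from 1149200 to 1156781 were 75.5-fold higher, 53.1-fold within the first set, at 0.711% ± 0.258 (SD, n = 2) of the reads in glycolate and 0.00585% in pyruvate (95% Wilson interval 0.00518 to 0.00661). The chromosome 2 window from 2239101 to 2307926 was 5.34-fold higher in glycolate than in pyruvate, with 35 of its 57 genes called higher and 0 lower.

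The 15 genes of chromosome 2 from 1620861 to 1652894 were 113-fold higher in pyruvate than in glycolate, and 158-fold within the first set, with 0.0306% ± 0.0104 (SD, n = 2) of the glycolate reads. Within them K788_006295 at 1622294 to 1624483 stood at 3209 CPM in pyruvate and 19.2 ± 5.34 CPM (SD, n = 2) in glycolate, a log2 fold change of -7.39 (SE 0.67) with an adjusted p of 0.0747 by edgeR's quasi-likelihood test. These were -7.76 and 0.000105 with the file set as a term. K788_006291 was again among the genes with the widest gap, at 61.3 ± 45.9 CPM (SD, n = 2) in glycolate, a log2 fold change of -7.50 (SE 1.27) and an adjusted p of 0.134 by edgeR. With the term these were -8.75 and 0.000184, and the log2 fold change was -6.91 without glycolate 1 and -8.67 without glycolate 2. Over all alternatives the adjusted p ran from 2.5e-25 to 0.09 for K788_006295 and from 1.01e-10 to 0.142 for K788_006291. Higher in glycolate with 0 pyruvate reads, K788_001177 on the plasmid at 1151483 to 1151689 was at least 39.9-fold higher on average and at least 20.5-fold within the first set. K788_0020435 was at least 69.1-fold higher on average and at least 3.3-fold within the first set. Their adjusted p values with the file set as a term were 0.00382 and 0.00811 by edgeR, and over all its alternatives they ran from 0.00293 to 0.364 and from 0.00811 to 0.647.

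With the file set as a term, 2009 genes were called between glycolate and pyruvate, 1155 higher and 854 lower in glycolate, all by at least 2-fold in that fit. The majority turned to 1101 higher and 1116 lower with DESeq2 size factors in place of TMM, and to 757 higher and 914 lower with DESeq2 in place of edgeR. The pyruvate library lay outside both glycolate libraries for 1122 of the 1155 and for 794 of the 854. It lay at least 2-fold beyond both for 917 of the 1155 and for 604 of the 854. Here too the genes were called from the same libraries, so the counts are no independent check. Without the term, edgeR called 0 genes, with 1652 at an unadjusted p under 0.05, while DESeq2 called 676, limma-voom 7, and edgeR 18 to 35 with any 1 replicated library left out. The median log2 fold change of all genes with the term was 0.24 under TMM and 0.08 under DESeq2 size factors, so folds near that shift depend on the scaling. The lone pyruvate library was assumed to vary like the others here too, with the same difference in ribosomal RNA reads, and within the first set glycolate was at least 4-fold higher for 1049 genes and at least 4-fold lower for 323.

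**Figure D3:**
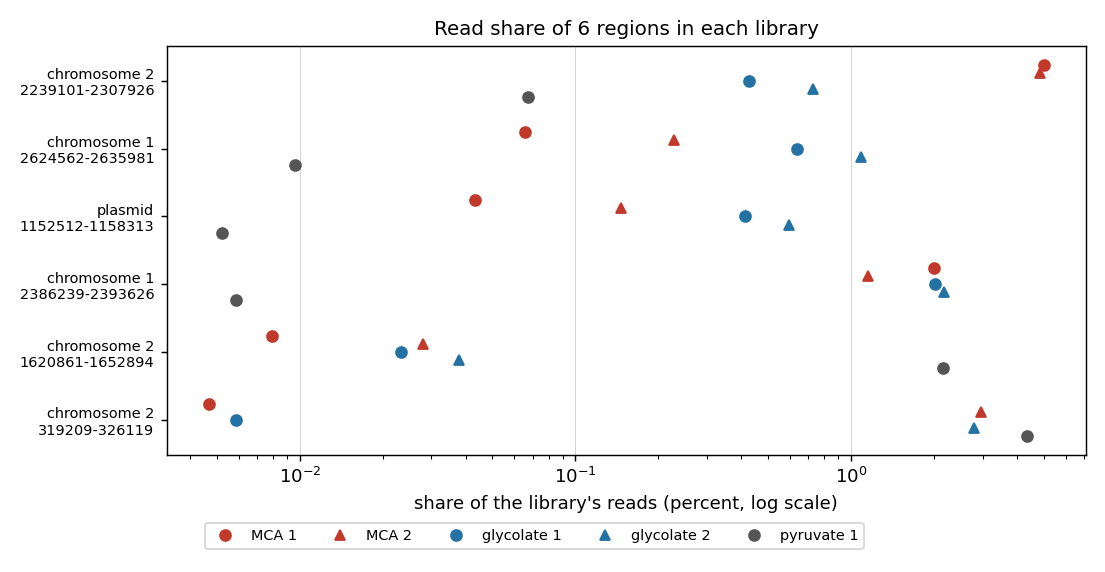
Share of each library's reads, in percent on a log scale (horizontal axis), taken by 6 regions (vertical axis, with replicon and position). Each point is 1 of the 5 libraries, circles for the first file set and triangles for the second; in the lowest region pyruvate lies with the second-set libraries and apart from MCA 1 and glycolate 1.

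The comparisons of MCA and of glycolate with pyruvate shared many of their genes. With the file set as a term, 546 genes were called higher than in pyruvate on both acids, where independent lists of 680 and 1155 would share 95.8, and 379 were called lower on both, where lists of 477 and 854 would share 49.7. The number called in opposite directions was 0. Simulated unchanged groups against a single simulated pyruvate library shared 0.15 calls on average and at most 1 over 20 simulations. Unchanged groups leave few calls to share, so that count is no baseline for lists of this length. The simulations used the dispersions of the fit with the term and gave pyruvate the mean levels of the first set. A pyruvate library that varied more was not simulated, so the simulated covariance may be too low. The covariance of the log2 fold changes was 3.08 against 0.431 in the simulations, a difference of 2.65. The single pyruvate library cannot be split, so part of the excess may come from it. In 370 genes both MCA and both glycolate libraries stood at least 4-fold above pyruvate, and in 46 genes at least 4-fold below it.

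The replicons carried different shares of the reads and of the calls. The plasmid took 5.62% ± 0.972 (SD, n = 2) of the reads in MCA, 8.76% ± 1.25 (SD, n = 2) in glycolate and 3.9% in pyruvate. The glycolate share was above the MCA share in both sets, at 9.64% against 4.93% in the first and 7.88% against 6.31% in the second, but 2 libraries against 2 cannot reach an exact two-sided permutation p below 0.333. Chromosome 1 held 39.3% of the genes tested, 67.3% of the calls lower in glycolate than in pyruvate and 31.9% of those higher. Chromosome 2 held 35.0% of the genes tested and 48.4% of the calls higher in MCA than in glycolate. Of these 74 calls, 28 were genes of the single window from 2239101 to 2307926. The plasmid held 25.7% of the genes tested and 9.8% of the calls higher in MCA than in glycolate, against 23.5% of those lower.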

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

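The tests in this part were chosen after their results were seen, except the test at equal depth and the test of whether pyruvate levels lay nearer to the second set, whose outcomes were still unknown.

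Some reads lay in features outside the comparisons, above what the floor of 3 reads would give. The labels name no library as a control. The 8 ribosomal RNA features of the first set held 0.282% of the counted reads in MCA 1 (95% Wilson interval 0.280 to 0.284), 0.359% in glycolate 1 (0.356 to 0.362) and 0.605% in pyruvate 1 (0.598 to 0.612). The ratio of reads in the feature named 16S_2 to those in 23S_2 was 0.735 in MCA 1, 0.567 in glycolate 1 and 14 in pyruvate 1, from 25038 and 1788 reads in the last. The 117 features listed only in the second set held 0.154% of the reads in MCA 2 and 0.171% in glycolate 2.

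Far more genes separated MCA from glycolate once the file set was a term. Changed feature boundaries as the whole cause are argued against, since 17.6% of the tested genes, all with the same length in both sets, were called between the sets where boundaries as the cause predicted under 5%. The lower depth of the second set is argued against too, because the differences between sets still correlated at 0.689 between MCA and glycolate with all libraries thinned to the same depth. A difference between the sets that both carbon sources share is consistent with a correlation of 0.729 before thinning. Whether it came from separate cultures, library preparation or the authors' processing stays open and was not tested.

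In the block of chromosome 2 from 319209 to 326119, the pyruvate library sat with the second set although it was counted with the first. The scaffolds and features used for counting are argued against as the cause, because the read share in pyruvate was 742 times the higher of those in MCA 1 and glycolate 1, which were counted on the same features. Over the 1446 genes called between the sets, 41.7% (95% Wilson interval 39.2 to 44.3) had a pyruvate level nearer to the second set, against 47.8% of the other genes. That interval includes the predicted minimum of 40%, so whether the set difference spares or includes the pyruvate library as a whole cannot be told apart. A biological difference of pyruvate-grown cells at these genes also stays open.

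The window of chromosome 2 from 2239101 to 2307926 was higher in MCA in both sets. A gain of 2-fold or more in copies of the whole window as 1 unit is argued against, because 25 of its 57 tested genes were under 2-fold. The window was drawn by joining called blocks, so the genes between them were uncalled by construction. A smaller gain was not tested, and 51 of the 57 genes were higher in MCA in both sets. Extra copies of single blocks were not tested and stay open. Size factors set by the most abundant genes are argued against, because at least 28 of its genes were called under DESeq2 size factors, under upper quartile size factors and without the 20 highest genes. A response to the carbon source stays open as an untested hypothesis, and 35 of the 57 genes were also called higher in glycolate than in pyruvate. Reads shared with similar genes elsewhere, and differences between single cultures, were not tested.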

How the results depend on the processing

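Without the file set term, edgeR called 0 genes in each comparison and 0 in the overlap. That count also came from DESeq2 size factors, upper quartile size factors, no filter, at least 50 reads in 2 libraries, all shared identifiers (chosen after the data were seen), the stricter overlap thresholds and, for MCA against glycolate, only its 4 libraries. In the order MCA against glycolate, MCA against pyruvate, glycolate against pyruvate and overlap, DESeq2 called 113, 297, 676 and 221, and limma-voom 5, 23, 7 and 7. Without the 20 highest genes edgeR called 2 genes between MCA and glycolate and 0 in the others. The replicate block, which is the file set, gave 413, 1157, 2009 and 925. The labels do not pair the libraries and there are only 2 pairs, whose differences between replicates 1 and 2 correlated across genes at 0.729. Leaving out each replicated library in turn gave 0 to 7, 5 to 72, 18 to 35 and 3 to 26: 2, 5, 35 and 3 without MCA 1, 0, 67, 18 and 11 without glycolate 1, 7, 19, 31 and 12 without MCA 2, and 0, 72, 32 and 26 without glycolate 2. The lone library was then assumed to vary like the others, and the cause of these changes was not tested. With the block, all settings chosen after the data were seen stayed within 1.5 times of 413, 1157 and 2009, except that equal depth gave 1049 between MCA and glycolate and 1780 between MCA and pyruvate, and the cause was not tested. Of the 413 genes, 412 were also called with DESeq2 size factors, 370 with DESeq2, 382 with limma-voom, 382 without the pyruvate library and 413 at equal depth. In the chromosome 2 window, 28 to 34 of the 57 genes were called under these settings. For the named genes, 118 of 160 settings stayed on their side of the threshold, 42 passed it and 0 reversed. The named genes were picked for large changes between groups that did not overlap, so reversals were unlikely by selection. Replicate correlations over all joined genes were 0.936 in MCA and 0.926 in glycolate. The gene lists, the removal of stable RNA features (none is named among the joined genes), pseudocounts (counts were used) and leaving out a replicated library with the block (0 residual degrees of freedom) were not run. The 4437531 reads of pyruvate limit low genes most.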

Other observations

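The hypothesis on gene position below was tested only after the blocks were seen, and the counts by order of the carbon sources were also chosen after the data were seen.

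Among genes called in more than 1 comparison, glycolate often stood above or below both other carbon sources. Of the 260 genes called lower in MCA than in glycolate with the file set as a term, 199 were also called higher in glycolate than in pyruvate, where independent lists would share 36.6 and simulated unchanged groups shared 0. In these 199 genes glycolate stood highest, and 61 of them were also called higher in MCA than in pyruvate. Of the 153 genes called higher in MCA than in glycolate, 53 were called lower in glycolate than in pyruvate, where independent lists would share 15.9, which put glycolate lowest. The order MCA above glycolate above pyruvate was called at each step in 21 genes, against 21.6 for independent lists and 0 in the simulations. The simulations also gave 0 for the 53 genes. Unchanged groups leave few calls to share, so these counts of 0 are no baseline for lists of this length. The simulations were those of the overlap, with no added spread in the pyruvate library. The comparisons share the glycolate libraries, which alone gave a covariance of -0.075 in the simulations against -0.535 in the data.

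Blocks seen against pyruvate reached beyond those of the report. On chromosome 2 from 2834627 to 2894857, 27 of 50 tested genes were called higher in glycolate than in pyruvate and 0 lower. Its 2 blocks differed between the glycolate libraries. The 11 genes from 2834627 to 2846587 held 0.159% of the reads in glycolate 1, 0.0125% in glycolate 2 and 0.00374% in pyruvate. The 10 genes from 2881218 to 2894857 held 0.01515%, 0.05098% and 0.001526% in the same order. On the plasmid from 1219471 to 1254228, 15 of 23 were called higher. That region held 0.108% of the reads in glycolate 1, 0.0844% in glycolate 2 and 0.00986% in pyruvate. Within it, the 4 genes from 1241643 to 1246329 held 0.0393% in glycolate 1 and 0.00674% in glycolate 2. On chromosome 1, 5 genes from 2030655 to 2033102 were 14.8-fold higher in pyruvate than in MCA and 11.4-fold higher than in glycolate, and 7 genes from 1529954 to 1535582 were 6.54-fold higher in pyruvate than in glycolate.

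A further hypothesis is that genes next to each other may share their response, as genes read from a common promoter would. If calls fell independently of position, shuffles of the calls within each replicon would often give as many blocks of at least 4 genes. Of 1000 shuffles, 0 did so in any of the 6 comparisons and directions, against 5 and 9 blocks higher and lower in MCA than in glycolate, 21 and 8 against pyruvate in MCA, and 48 and 25 in glycolate. The longest block held 22 genes. In some blocks the second-set library lay on the other side of pyruvate. The chromosome 2 block from 1754193 to 1758312 was called lower in glycolate than in pyruvate. It held 0.0101% of the reads in glycolate 1, 0.158% in glycolate 2 and 0.0481% in pyruvate. The block from 1755758 to 1759209, called lower in MCA, held 0.00536% in MCA 1, 0.114% in MCA 2 and 0.0418% in pyruvate. Between 9.64% and 22.9% of the calls of a comparison and direction lay in such blocks, so most calls stood outside them. Reads that run from a gene into its neighbour would give blocks too and were not tested.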
